A study of Mus musculus with 16 samples.

How the data were processed

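RNA was measured in adult mouse cardiomyocytes from 16 libraries in 4 groups of 4, which cross the injected virus (AAV9-Vector or AAV9-PRODH) with the surgery (sham or TAC). Per the labels' protocols, RNA was taken up in TRIzol and treated with DNase I, and libraries were made with a SMARTER mRNA-Seq kit. The authors deposited a table of estimated (expected) counts per gene and library, which need not be whole numbers, beside their own group means and gene lengths, which were not used here. Of the 57010 gene models in it, 9538 (16.73%) have a fractional count in at least 1 library, so the counting divided some reads between similar sequences. The aligner, the counting tool, the annotation and the genome build are not given in the sources used here, so no coordinates are printed. All 16 columns were matched to a sample by name. Gene symbols are those of the deposited table, in which 1903 gene models have no symbol or a repeated one. GENCODE M21 was used only for transcript types and to find nuclear copies of mitochondrial genes, and 52029 of the gene identifiers are in it.

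Groups came from the sample labels. Total counts ran from 15987580 to 22680212 per library, and 18346 to 20445 genes had a count. Genes of the mitochondrial genome and nuclear pseudogenes of the same sequence took 54.8% to 61.2% of the counts as group means. The largest of these copies were Gm28437 (8.43% of all counts), Gm28661 (5.77%), Gm10925 (3.46%), Gm29216 (1.77%) and Gm28438 (0.818%). Counts outside them set the depth for other genes. No pair of libraries in a group held the same counts: over genes with a summed count of at least 20 the chi-square per gene was 2.87 to 30.7.

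Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and data.table (version 1.17.8). Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 14066, and libraries were scaled by TMM. A quasi-likelihood model with robust spread was fitted to all 16 libraries with the 4 groups and no block. It gave TAC against sham within each virus, PRODH against vector within each surgery, and their interaction. P-values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Normalised CPM, counts scaled to a common library total, were computed here from the deposited estimated counts with TMM factors, and fitted folds used a prior count of 0.125. Standard errors (SE) belong to log2 fold changes, and standard deviations (SD) to CPM of the 4 libraries of a group.

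The 28 gene lists, the comparisons, the test, the rule for named genes and most of the alternatives were chosen before the data were examined. The lists cover hypertrophy and stress, adult contractile and calcium genes, proline and glutamate, fatty acid oxidation, the citric acid cycle, nuclear and mitochondrial respiratory genes, glycolysis, branched-chain amino acids, matrix, the ATF4 response, the unfolded protein response, antioxidant genes, p53 and senescence, interferon, inflammation, genes induced by cell isolation, cell cycle, clock and ribosomal proteins. They also hold markers of fibroblasts, endothelium, mural cells, myeloid cells, lymphoid cells, red cells and platelets, glia and mesothelium, and of atrial and conduction tissue. Each list was tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 28 lists, with an estimated correlation as an alternative. The other alternative was fry, which tests whether a list's genes move one way on balance and compares them with no other genes. The smallest list had 3 measured members. Counts are given over all genes and adjusted over the list alone.

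Named genes were Prodh in every comparison and, in both main comparisons, 12 landmark genes and up to 3 members per list with the smallest p. They also were the 6 largest rises and 6 largest falls there, and 3 and 3 in other comparisons, among called genes with a standard symbol and at least 5 CPM over all 16 libraries whose groups did not overlap (no such condition for the interaction). List members came only from lists that passed camera or had at least 3 called members, and fewer than 3 were taken per list. Of the list members taken up, the text names a part.

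The test was tried on simulated counts with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. Counts were drawn from each gene's mean over all 16 libraries, its spread and the real library sizes. All other genes had equal means in the 4 groups, so fewer genes changed than were called in the real comparisons. In the simulated TAC comparison under the vector, over 13798 genes, the test recovered 64.2%, 74.6% and 93.9% of the changed genes at these sizes, with 7.19% of calls false. For PRODH against vector after TAC, over 13762 genes, the shares were 62.7%, 85.1% and 92.4%, with 3.61% false. For TAC under PRODH, over 13748 genes, they were 53.7%, 82.1% and 97.0%, with 6.06% false. For PRODH after sham, over 13766 genes, they were 55.2%, 85.1% and 97.0%, with 4.24% false. For the interaction, over 13763 genes, they were 35.8%, 83.6% and 89.4%, with 7.95% false.

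Alternatives were DESeq2 1.42.0 (size factors and Wald test), limma voom, library size without scaling factors, no low-count filter, a filter of 1 CPM in 4 libraries, a log2 threshold of 1, only the groups compared, a spread that was not robust, leaving out Prodh and mitochondrial genes, the replicate number as a block, and each library left out in turn. After seeing the data 3 more were added: leaving out mitochondrial genes with their nuclear copies, leaving out vector TAC libraries 3 and 4, and a fibroblast-marker score per library as a covariate. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.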

Results

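Gene expression was measured by RNA sequencing in cardiomyocytes isolated from the hearts of adult C57BL/6 mice. The animals had received adeno-associated virus 9 (AAV9), a gene delivery vehicle, as a control vector or carrying PRODH. PRODH is proline dehydrogenase, the mitochondrial enzyme that takes the first step of proline oxidation. Transverse aortic constriction (TAC), which narrows the aorta and loads the heart with pressure, or a sham operation followed 3 weeks after the injection. Cells were collected 4 weeks after surgery. The 16 libraries fall into 4 groups of 4: vector sham, vector TAC, PRODH sham and PRODH TAC. The total count per library ranged from 15987580 to 22680212. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

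Genes of the mitochondrial genome took 40.1% ± 1.49 (SD, n = 4) of the counts in vector sham, 35.1% ± 0.620 in vector TAC, 39.8% ± 0.405 in PRODH sham and 35.5% ± 0.772 in PRODH TAC. With nuclear pseudogenes that share their sequence, the shares came to 61.2%, 54.8%, 60.9% and 55.0%. The first principal component of all tested genes held 48.7% of the variance and set the vector TAC libraries (49.5 to 61.1) apart from both sham groups (-41.8 to -26.6), with the PRODH TAC libraries between them (1.24 to 11.7). In vector TAC, libraries 3 and 4 had 20080 and 22060 CPM (counts scaled to a common library total) of mt-Nd4, against at least 25950 in the other 14 libraries.

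Prodh (ENSMUSG00000003526), the gene that the virus was meant to raise, was measured first. It stood at 10.95 CPM ± 0.454 (SD, n = 4) in vector sham, 7.28 ± 1.18 in vector TAC, 13.8 ± 0.955 in PRODH sham and 13.6 ± 1.05 in PRODH TAC. After TAC it was 1.86 times as high with the PRODH virus as with the vector (log2 fold change 0.90 ± 0.10 SE, edgeR Benjamini-Hochberg adjusted p = 2.19e-08). All 4 PRODH TAC libraries lay above all 4 vector TAC libraries. After sham the difference of 0.33 ± 0.10 missed the threshold (adjusted p = 0.0517). TAC lowered Prodh in vector hearts (-0.58 ± 0.11, adjusted p = 2.58e-05), a call lost when scaled by library size alone (-0.23, adjusted p = 0.0798). The value in PRODH hearts was -0.02 ± 0.10 (adjusted p = 0.904), and these TAC effects differed (0.56 ± 0.14, adjusted p = 0.00373). Scaled by library size alone, the TAC effect in PRODH hearts turned to 0.36 (adjusted p = 0.00394). The sham difference passed when only the sham groups were fitted (adjusted p = 0.0438), without PRODH sham library 1 (0.0457) and without vector TAC library 1, 2, 3 or 4 (0.0477, 0.0338, 0.0448 and 0.0482). The counts show the virus only as far as its transcript matches the mouse gene model, since the sequence it carries is not given in the sources used here.

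**Figure D1:**
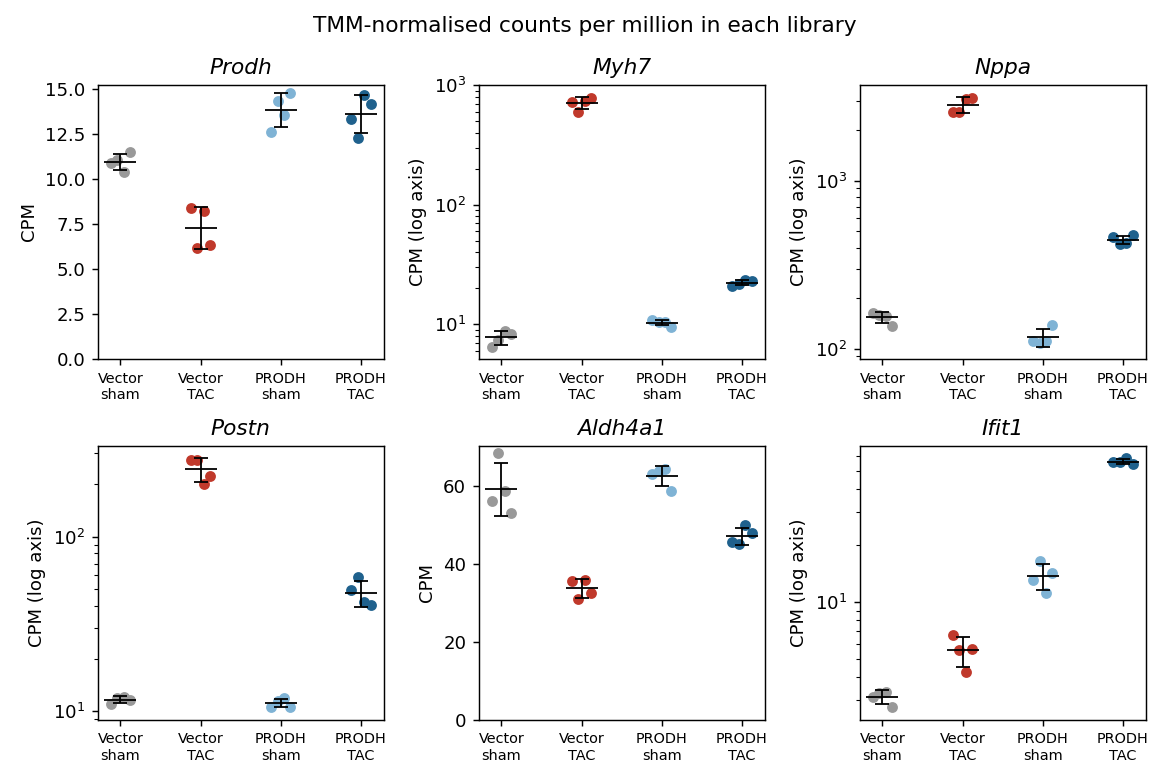
TMM-normalised CPM of Prodh, Myh7, Nppa, Postn, Aldh4a1 and Ifit1 in each of the 16 libraries, with the mean and SD (n = 4) of each group as black bars; the axes of Myh7, Nppa, Postn and Ifit1 are logarithmic. Mean Myh7 was 711 CPM in vector TAC and 22.2 CPM in PRODH TAC, while mean Ifit1 was 5.53 and 55.8 CPM.

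The first comparison the study set out to make asks how pressure overload changed cardiomyocyte expression under the control vector. Genes of the hypertrophic and wall-stress response rose together. Of 19 measured members 18 were higher after TAC and none was lower, 18 also adjusted over the list alone. Myh7, the slow fetal myosin heavy chain, went from 7.72 ± 0.999 to 711 ± 80.7 CPM (SD, n = 4), and Nppa, which encodes atrial natriuretic peptide, from 154 ± 11.8 to 2827 ± 304 CPM. Nppb, the B-type natriuretic peptide gene, rose by 2.24 ± 0.08 (log2 ± SE), the skeletal actin gene Acta1 by 2.45 ± 0.09 and the matricellular gene Ccn2 by 3.17 ± 0.07. Of 25 genes for the adult sarcomere, calcium handling and ion channels, 21 fell and 1 rose, with the same counts adjusted over the list alone. Scaled by library size alone, 11 of them fell and 4 rose, and the median went from -0.38 to -0.03, with Myh6 at -0.25. They included the calcium pump Atp2a2 (-1.18 ± 0.07), the fast myosin Myh6 (-0.61 ± 0.08) and the potassium channel genes Kcnd2 (-1.66 ± 0.11) and Kcnv2 (-2.25 ± 0.16). Every named gene had an edgeR adjusted p of 1.47e-07 or less, as given for Myh6. Both lists passed the set test (camera, adjusted p = 4.01e-58 and 8.31e-10) and held with an estimated correlation between genes (adjusted p = 1.12e-07 and 0.00659). Myh6, Myh7 and Nppa had fractional counts in 16, 16 and 15 libraries. Reads shared with similar sequences make their absolute levels less certain.

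Extracellular matrix genes rose in full: all 36 measured members were higher after TAC, 36 also adjusted over the list alone, with a median log2 fold change of 3.08. Periostin (Postn), a matrix protein of activated fibroblasts, went from 11.6 ± 0.505 to 243 ± 38.0 CPM (SD, n = 4), and type I collagen (Col1a1) from 15.3 ± 3.13 to 210 ± 29.7 CPM. The largest rises among genes of at least 5 CPM with a standard symbol were Myh7 (6.52 ± 0.10, log2 ± SE), Comp (6.21 ± 0.18), Cilp (5.62 ± 0.13), Ltbp2 (5.58 ± 0.16), Thbs4 (5.30 ± 0.13) and Svep1 (4.55 ± 0.15), of which all but Myh7 encode extracellular proteins. Markers of cells other than cardiomyocytes moved in the same comparison. All 16 fibroblast markers rose (median 2.25), among them Mfap5 (4.12 ± 0.12) and Pi16 (3.13 ± 0.11). All 19 endothelial markers rose (median 1.06), among them Pecam1 (1.18 ± 0.09). Of 21 myeloid markers 19 rose (median 1.32), with C1qb at 1.39 ± 0.10. Of 14 mural markers 10 rose and 2 fell, with Pdgfrb at 1.58 ± 0.10. All 6 measured red cell and platelet markers and all 3 lymphoid markers rose, as did 4 of 9 glial and mesothelial ones. All these counts were the same adjusted over the list alone. Under library size alone 12 mural and 7 glial and mesothelial markers were higher, with 2 and 0 lower. The matrix, fibroblast and endothelial lists passed camera (adjusted p = 1.44e-123, 2.38e-39 and 1.96e-13) and held with an estimated correlation (adjusted p = 2.60e-04, 0.00142 and 0.0424). The myeloid, mural and red cell lists passed (adjusted p = 4.77e-09, 0.00214 and 0.0341) but gave an adjusted p = 0.0523, 0.16 and 0.328 with an estimated correlation. The lymphoid and glial lists did not pass (0.0853 and 0.404).

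Genes of mitochondrial fuel use fell after TAC. Of 30 genes for fatty acid uptake and oxidation 28 fell and 1 rose, including the uncoupling protein gene Ucp3 (33.0 ± 3.02 to 6.75 ± 0.465 CPM, SD, n = 4) and the thiolase gene Acaa2 (-1.19 ± 0.07, log2 ± SE). In the citric acid cycle 25 of 26 genes fell, with the succinate dehydrogenase subunit Sdha at -0.95 ± 0.08. In branched-chain amino acid breakdown 19 of 21 fell, with Aldh6a1 at -0.95 ± 0.07. All 42 nuclear genes of the respiratory chain fell (Cox7a1 at -1.04 ± 0.09), and so did all 13 protein genes of the mitochondrial genome (mt-Nd2 at -0.82 ± 0.08). Counts adjusted over the list alone were 29 lower and 1 higher for fatty acids and unchanged for the rest. Scaled by library size alone, lower and higher genes numbered 24 and 1 for fatty acids, 18 and 1 for the citric acid cycle, and 17 and 2 for branched-chain breakdown. In the respiratory chain they numbered 29 and 0 for nuclear genes and 9 and 0 for mitochondrial ones. The 5 medians went from -0.83, -0.64, -0.77, -0.62 and -0.65 to -0.47, -0.28, -0.41, -0.27 and -0.30. Sdha, Aldh6a1, Cox7a1 and mt-Nd2 then stood at -0.59, -0.60, -0.68 and -0.47. All 5 lists passed camera (adjusted p = 7.56e-23, 1.18e-13, 6.20e-12, 8.17e-16 and 4.34e-06, in the order given). The fatty acid, citric acid and branched-chain lists held with an estimated correlation (adjusted p = 0.00648, 0.0340 and 0.0121). The respiratory chain lists gave an adjusted p = 0.134 for nuclear genes and 0.0650 for mitochondrial ones with an estimated correlation. Fibroblast and endothelial markers rose in the same libraries, as given for the matrix.

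In proline and glutamate metabolism, the theme of the study, 7 of 22 genes rose and 9 fell. The list did not pass when tested against all other genes (camera adjusted p = 0.313). Tested by fry for moving one way on balance, it pointed down (adjusted p = 0.00567), with a mean log2 fold change of -0.004. Such a call is not particular to this list. Fry also passed other lists that camera did not call here, such as ATF4 (adjusted p = 4.43e-07), p53 (1.56e-07) and clock genes (3.38e-06), all pointing up. The list median of -0.07 turned to 0.28 when scaled by library size alone, with 11 higher and 4 lower. Slc1a5, a glutamine transporter, rose by 1.94 ± 0.14 (log2 ± SE) and Aldh18a1, which begins proline synthesis, by 0.66 ± 0.14. Aldh4a1, which acts after Prodh in proline breakdown, fell from 59.0 ± 6.68 to 33.7 ± 2.45 CPM (SD, n = 4), and the transaminase Got1 fell by 0.75 on the log2 scale. Pycr1, the last enzyme of proline synthesis, was at 0.68 ± 0.32 (adjusted p = 0.0711), and passed without vector sham library 2 (0.0234) and with library size alone (1.03, adjusted p = 0.00822). That scaling put Aldh18a1 at 1.01, Aldh4a1 at -0.46 and Got1 at -0.40. The counts adjusted over the list alone were again 7 and 9.

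Interferon-response genes rose after TAC (26 of 27, median 0.80), as did cell cycle genes (24 of 28, median 0.92), with Ifit3 at 1.27 ± 0.10 and the replication gene Mcm6 at 1.10 ± 0.14 (log2 ± SE, n = 4). Both lists passed camera (adjusted p = 3.89e-07 and 0.00431) and held with an estimated correlation (adjusted p = 0.0424 and 0.0198). In the same libraries 19 of 21 myeloid, all 19 endothelial and all 16 fibroblast markers rose (medians 1.32, 1.06 and 2.25). Inflammatory mediators rose in 14 of 25 cases and fell in 1 (adjusted p = 0.00110), and genes that cell isolation is known to induce rose in 14 of 25 and fell in 3 (adjusted p = 0.0433), but with an estimated correlation the adjusted p = 0.155 and 0.278. Under library size alone 19 and 22 of them were higher and 0 and 1 lower, with medians of 0.94 and 0.65 against 0.59 and 0.30. The isolation list was lost without vector sham library 1, PRODH sham libraries 2 or 3, or vector TAC library 2 (adjusted p = 0.0852, 0.0552, 0.0551 and 0.0733). It held Hspa1b, a heat shock gene with reads shared with a near copy, at 1.18 ± 0.07 and Hsph1, another, at -1.44 ± 0.08. Glycolysis genes fell in 12 of 24 cases and rose in 6 (median -0.19, turning to 0.16 with 12 higher and 6 lower when scaled by library size alone; adjusted p = 0.0163). That call gave an adjusted p = 0.413 with an estimated correlation.

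Lists without a set call still held single genes that moved after TAC. Of 22 genes of the ATF4 amino acid response 13 rose and 5 fell, led by Nupr1 (0.795 ± 0.116 to 6.05 ± 0.285 CPM, SD, n = 4). Of 24 p53, apoptosis and senescence genes 13 rose and 7 fell, with the cell cycle inhibitor Cdkn1a at 0.92 ± 0.08 (log2 ± SE). Of 18 clock genes 13 rose and 3 fell, with Cry1 at 1.46 ± 0.11 and Nr1d1 at -1.13 ± 0.09. Of 27 antioxidant genes 5 rose and 15 fell, with Gpx3 at 1.11 ± 0.08, while the list median of -0.29 turned to 0.07 under library size alone, with 12 higher and 3 lower. Unfolded protein genes rose in 5 and fell in 7 of 20 cases, ribosomal protein genes in 2 and 3 of 36, and atrial and conduction genes in 5 and 3 of 11. Rpl3, a ribosomal protein gene, was at 1.10 ± 0.08, while the ribosomal median of -0.01 turned to 0.34 under library size alone, with 32 higher and none lower. For the unfolded protein list the median was 0.02 (-0.004 with DESeq2 size factors) and the mean -0.04. Under library size alone its median was 0.37, with 12 higher and 2 lower. That scaling gave 16 higher and 5 lower ATF4 genes, 15 and 2 p53, 14 and 3 clock, and 7 and 3 atrial genes. The ribosomal list stood at -0.01 and 0.01 and the atrial list at 0.27 and -0.03, so their signs differ. Camera gave an adjusted p of 0.303, 0.167, 0.222, 0.128, 0.303, 0.662 and 0.498 for these lists in the order given. Adjusted over the list alone the antioxidant count was 6 higher and 15 lower, the ribosomal count 1 and 1, and the inflammatory count 15 and 1; the other lists kept their counts.

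In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 7949 of 14066 genes after TAC under the vector, 4263 higher and 3686 lower. A change of at least 1 on the log2 scale was found for 1763 higher and 482 lower genes. The largest falls among genes of at least 5 CPM with a standard symbol were Klhl33 (-2.63 ± 0.12, log2 ± SE), Acot1 (-2.33 ± 0.14), Ucp3 (-2.29 ± 0.09), Chaer1 (-2.28 ± 0.14), Kcnv2 (-2.25 ± 0.16) and Phkg1 (-2.21 ± 0.10). Below that level the atrial gene Bmp10 was at -3.94 ± 0.27, which rests on its level in vector sham. Acot1 and Phkg1 shared reads with similar sequences in 16 and 15 libraries. Scaling by library size alone moved the median of all genes from 0.02 to 0.37. The split moved to 7474 higher and 1198 lower genes, or 86.2% higher against 53.6%. With the fibroblast-marker score as a covariate 7 genes were called, and the score has 1.73% of its variance within groups.

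The second comparison the study set out to make asks how the PRODH and vector arms differed after TAC. All 19 hypertrophy and stress genes were lower with PRODH, 19 also adjusted over the list alone. Myh7 was at 711 ± 80.7 CPM (SD, n = 4) in vector TAC and 22.2 ± 1.06 in PRODH TAC, a log2 difference of -5.00 ± 0.09 (SE), and Nppa at 2827 ± 304 and 446 ± 25.4 CPM. Nppb differed by -1.16 ± 0.07, Acta1 by -0.86 ± 0.09 and Ccn2 by -2.62 ± 0.07. Of the 25 contractile, calcium and channel genes 15 were higher and 2 lower (15 and 3 adjusted over the list alone), with Kcnv2 at 1.76 ± 0.16, Kcnj3 at 1.31 ± 0.10, Atp2a2 at 0.65 ± 0.07 and Myh6 at 0.49 ± 0.08. Camera called both lists (adjusted p = 4.44e-55 and 2.98e-07), and both held with an estimated correlation (adjusted p = 2.20e-08 and 0.0188).

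Matrix genes were lower with PRODH after TAC in all 36 cases (median -1.93), 36 also adjusted over the list alone. The largest falls among genes of at least 5 CPM with a standard symbol were Comp (34.7 ± 5.37 to 1.01 ± 0.121 CPM, SD, n = 4), Myh7, Fmod (-3.99 ± 0.15, log2 ± SE), Ltbp2 (-3.84 ± 0.13), Thbs4 (-3.84 ± 0.11) and the collagen crosslinking enzyme Lox (-3.55 ± 0.14). Postn differed by -2.35 ± 0.10 and Col1a1 by -2.44 ± 0.11. Other cell types' markers again moved with them. All 16 fibroblast markers were lower (median -1.39), with Mfap5 at -2.66 ± 0.10 and Pi16 at -2.15 ± 0.10. So were 18 of 19 endothelial markers (median -0.45), with the fenestral diaphragm gene Plvap at -2.10 ± 0.13. Of the myeloid markers 20 of 21 were lower (median -0.79, C1qb at -0.81 ± 0.09). Of the mural markers 7 of 14 were lower and 2 higher (Pdgfrb at -0.57 ± 0.09), and all 6 red cell and platelet markers were lower (Hbb-bs at -1.14 ± 0.13). Of 9 glial and mesothelial markers 5 were lower, and of 3 lymphoid markers 2. When adjusted over the list alone, mural markers were 9 lower and 2 higher, glial ones 6 lower, and the rest unchanged. The matrix and fibroblast lists passed camera (adjusted p = 1.82e-116 and 1.06e-32) and held with an estimated correlation (adjusted p = 2.09e-04 and 0.00316). The endothelial, myeloid and red cell lists passed (adjusted p = 2.73e-07, 2.73e-07 and 7.85e-05) but gave an adjusted p = 0.136, 0.0924 and 0.113 with an estimated correlation. The mural, glial and lymphoid lists did not pass (0.373, 0.161 and 0.373).

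Several fuel genes were higher with PRODH after TAC. In the same comparison all 16 fibroblast, 18 of 19 endothelial and 20 of 21 myeloid markers were lower (medians -1.39, -0.45 and -0.79). Of the fatty acid genes 23 of 30 were higher and 1 lower (median 0.29), with Ucp3 at 6.75 ± 0.465 CPM (SD, n = 4) in vector TAC and 14.3 ± 0.506 in PRODH TAC and the acyl-CoA synthetase Acsl1 at 0.60 ± 0.07 (log2 ± SE). In the citric acid cycle 15 of 26 were higher and 1 lower, with Sdha at 0.50 ± 0.08. In branched-chain amino acid breakdown 15 of 21 were higher and 1 lower, with Aldh6a1 at 0.59 ± 0.07. These 3 lists passed camera (adjusted p = 2.44e-07, 6.73e-05 and 2.86e-06), but with an estimated correlation the adjusted p = 0.0924, 0.211 and 0.0751. In the respiratory chain 11 of 42 nuclear genes were higher and 3 lower, with Ndufs1 at 0.66 ± 0.10 and Cox7a1 at 0.17 ± 0.09 (adjusted p = 0.138). Of the 13 mitochondrial genes 2 were higher (6 under library size alone), with mt-Nd2 at 0.13 ± 0.08 (adjusted p = 0.205). Neither list passed (camera adjusted p = 0.171 and 0.357). In proline and glutamate metabolism 5 of 22 genes were higher and 6 lower, with Aldh4a1 at 0.48 ± 0.08, Slc1a5 at -1.29 ± 0.12, Aldh18a1 at -0.51 ± 0.13 and Pycr1 at -0.35 ± 0.29 (adjusted p = 0.35). The Aldh18a1 call was lost without vector TAC libraries 3 and 4 (adjusted p = 0.128). The list did not pass (adjusted p = 0.825). Its median was 0.004 and its mean -0.04. The proline list, adjusted over the list alone, had 5 higher and 7 lower, and the other lists of this group kept their counts.

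Interferon-response genes were higher with PRODH after TAC, in 22 of 27 cases with none lower (23 and 1 adjusted over the list alone; median 1.39). Ifit1, an antiviral RNA-binding protein, went from 5.53 ± 0.997 CPM (SD, n = 4) in vector TAC to 55.8 ± 1.80 in PRODH TAC. The 6 largest rises among genes of at least 5 CPM with a standard symbol, each an interferon-stimulated gene, were Ifit1 (3.32 ± 0.11, log2 ± SE), Ddx60 (3.08 ± 0.15), Ifi44 (2.72 ± 0.12), Usp18 (2.57 ± 0.10), the transcription factor Irf7 (2.29 ± 0.08) and Ifit3b (2.19 ± 0.14), the last with reads shared with a near copy in all 16 libraries. The list passed camera (adjusted p = 2.66e-49) and held with an estimated correlation (7.08e-05), while the myeloid markers were lower in the same comparison.

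Inflammatory mediators were lower in 19 of 25 cases and genes that cell isolation induces in 20 of 25, with 1 of the latter higher. Nr4a1, an immediate early gene, was at 33.2 ± 1.81 CPM (SD, n = 4) in vector TAC and 15.4 ± 0.760 in PRODH TAC, and Hspa1b differed by -0.83 ± 0.07 (log2 ± SE). Both lists passed (camera adjusted p = 2.73e-07 and 1.92e-10) and held with an estimated correlation (adjusted p = 0.0473 and 0.00640). Of the p53 and senescence genes 11 of 24 were lower and 3 higher, with Cdkn1a at -1.53 ± 0.08 (adjusted p = 0.0139 for the list, and adjusted p = 0.0581 with an estimated correlation). Ribosomal protein genes were lower in 29 of 36 cases and higher in none, with Rpl3 at -0.95 ± 0.07 and Rps20 at -0.69 ± 0.08 (adjusted p = 2.98e-07 for the list, and adjusted p = 0.297 with an estimated correlation).

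The remaining lists did not pass between the virus arms after TAC. Higher and lower genes numbered 2 and 7 of 22 in the ATF4 response (Nupr1 at -2.95 ± 0.19, log2 ± SE), 3 and 10 of 20 in the unfolded protein response, 4 and 12 of 27 among antioxidant genes (Gpx3 at -1.31 ± 0.08) and 7 and 9 of 24 in glycolysis. They numbered 5 and 1 of 28 in the cell cycle (Mki67 at 0.76 ± 0.15), 5 and 8 of 18 in the clock (Tef at 0.75 ± 0.07, Arntl at -1.36 ± 0.14) and 5 and 3 of 11 among atrial genes. Camera gave an adjusted p of 0.0612, 0.170, 0.234, 0.971, 0.156, 0.565 and 0.971. The ATF4 value fell to 0.0443, 0.0493 and 0.0446 without vector sham library 3, vector sham library 4 or PRODH TAC library 2. The glycolysis median was -0.08 and its test pointed up, and the atrial median was 0.32 with a mean of -0.05. Adjusted over the list alone, the isolation list had 2 higher and 23 lower, the p53 list 3 and 12, the unfolded protein list 3 and 12, glycolysis 8 and 11, the cell cycle 4 and 1, and the other lists of these last paragraphs kept their counts.

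The edgeR test with Benjamini-Hochberg adjustment called 6059 of 14066 genes between the virus arms after TAC, 2603 higher and 3456 lower with PRODH, of which 373 and 709 differed by at least 1 on the log2 scale. With the fibroblast-marker score as a covariate 40 genes were called, while the median SE of the 6059 genes went from 0.11 to 0.51. The score has 1.73% of its variance within groups, so this fit cannot part it from the virus arms.

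**Figure D2:**
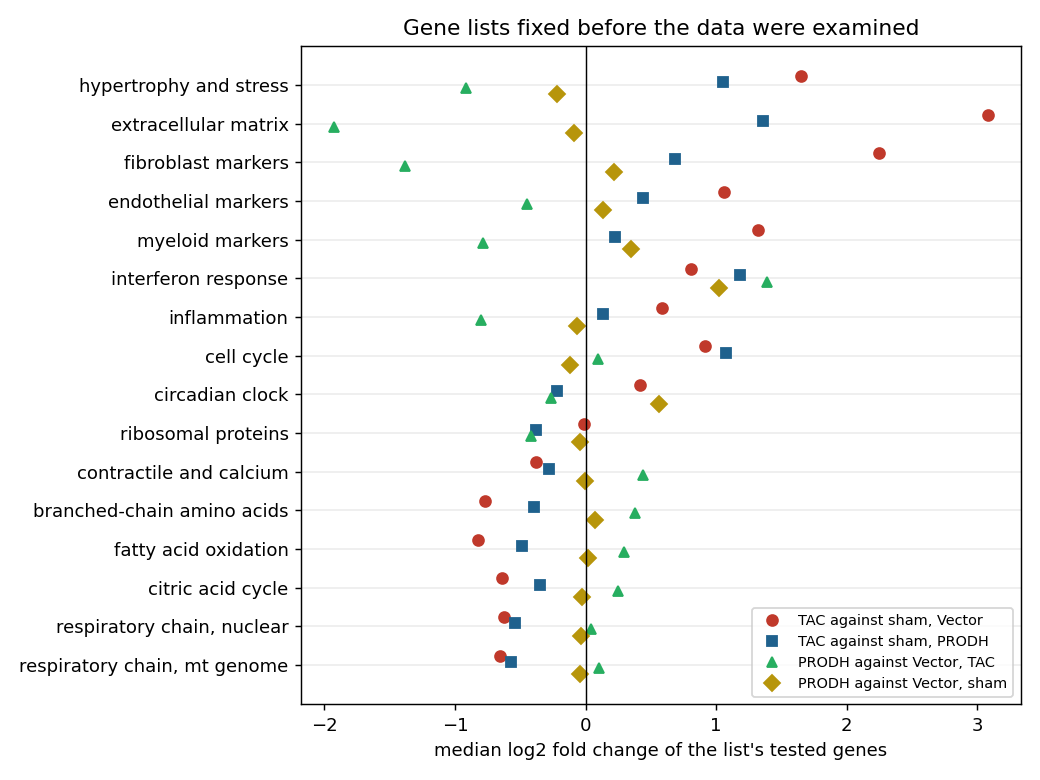
Median log2 fold change of the measured genes of 16 lists in 4 comparisons, one symbol per comparison, with 0 as a vertical line. Matrix genes stood at 3.08 for TAC against sham under the vector and at -1.93 for PRODH against vector after TAC; with library size alone as scaling, the TAC medians turned sign for ribosomal genes under the vector (to 0.34) and, under PRODH, for contractile (to 0.09), citric acid (to 0.03), clock (to 0.15) and ribosomal genes (to 0.004), and the PRODH median after sham for contractile genes (to 0.02).

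The next question is how many of the genes that TAC changed differed the other way between the virus arms after TAC. Of the genes called after TAC under the vector, 53.4% were also called the opposite way between the virus arms after TAC. These were 2534 genes that were higher after TAC and lower with PRODH, such as Myh7, Comp, Nppa and Postn, and 1708 that were lower after TAC and higher with PRODH, such as Atp2a2, Ucp3 and Klhl33. A further 292 were called the same way in both, 153 higher and 139 lower. The overlap was not computed with library size alone. That scaling called 1198 genes lower after TAC under the vector, fewer than the 1708, so this count depends on the scaling. Independent lists of the same lengths would give 1047 and 682 opposite genes and 789 and 906 genes called the same way. Both comparisons use the vector TAC libraries, which alone makes fold changes run opposite ways. Across genes, which are not independent replicates, the correlation was -0.72 against -0.50 in 20 simulations with no effect. The shared libraries alone fix that simulated value, so the -0.50 is not the part of -0.72 that they explain. The covariance was -0.345 against -0.0195, a difference of -0.326. With the vector TAC libraries split into 2 and 2, so that none was shared, the 6 ways gave 2983 to 3441 opposite genes, 150 to 335 in the same direction and correlations of -0.68 to -0.60. The excess over either reference is not an estimate of a shared effect.

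The same surgery contrast under PRODH shows what TAC changed in that arm. Matrix genes rose in 34 of 36 cases (median 1.36), with the proteins Cilp (2.29 ± 0.563 to 15.1 ± 2.15 CPM, SD, n = 4), Ltbp2 (2.36 ± 0.24, log2 ± SE) and Postn (2.10 ± 0.12) as the largest rises among genes of at least 5 CPM. Among those with a standard symbol the largest falls were Dbp (-1.77 ± 0.08) and Nr1d1 (-1.59 ± 0.09), both of the circadian clock and both with fractional counts in all 16 libraries, and the desaturase Scd4 (-1.54 ± 0.12). The level of at least 5 CPM is a mean over all 16 libraries. Ltbp2 was at 0.665 CPM in PRODH sham and 3.47 in PRODH TAC, and reached that level through vector TAC (49.8 CPM). Hypertrophy genes rose in 17 of 19 cases and fell in 1. Nppa (1.93 ± 0.09), Myh7 (1.11 ± 0.10) and Col1a1 (1.29 ± 0.12) are named after their values were seen, for comparison with the vector arm. Interferon genes rose in all 27 cases (median 1.18), cell cycle genes in 23 of 28 (median 1.08) and mural markers in 12 of 14. These 5 lists passed camera (adjusted p = 2.55e-64, 3.05e-36, 1.02e-53, 1.52e-13 and 7.03e-07, in the order given) and held with an estimated correlation (0.00256, 1.80e-06, 2.36e-05, 2.36e-05 and 0.0391). Fibroblast markers rose in 12 of 16 cases, endothelial ones in 13 of 19, red cell and platelet ones in 4 of 6 and atrial genes in 6 of 11 with 1 lower. These passed (adjusted p = 4.05e-11, 5.39e-08, 0.0199 and 7.02e-05), but with an estimated correlation the adjusted p = 0.0563, 0.104, 0.299 and 0.0563. Under library size alone 16, 19, 5 and 8 of them were higher and none lower.

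Falls under PRODH after TAC covered fatty acid genes (26 of 30), branched-chain genes (20 of 21), nuclear respiratory genes (40 of 42) and mitochondrial ones (12 of 13), with no member higher. Scaled by library size alone, lower and higher genes in these lists numbered 11 and 3, 3 and 0, 20 and 1, and 5 and 0. Their medians went from -0.49, -0.39, -0.54 and -0.57 to -0.11, -0.01, -0.16 and -0.18. Citric acid genes fell in 21 of 26 cases and contractile genes in 14 of 25 with 2 higher, though their medians of -0.35 and -0.28 turned to 0.03 (5 higher, 4 lower) and 0.09 (11 and 3) under library size alone. Clock genes fell in 9 and rose in 5 of 18 (median -0.22, turning to 0.15 with 3 lower and 8 higher). These 7 lists passed camera (adjusted p = 7.54e-26, 9.53e-12, 3.81e-29, 3.38e-09, 7.89e-13, 4.99e-05 and 8.03e-05) and held with an estimated correlation (0.00256, 0.0123, 0.0383, 0.0249, 0.0349, 0.0373 and 0.0123). Glycolysis genes fell in 17 and rose in 2 of 24, antioxidant genes in 16 and 1 of 27 and ribosomal genes in 28 and 0 of 36, with medians of -0.30, -0.32 and -0.38 that turned to 0.09, 0.07 and 0.004. Under library size alone 7, 8 and 8 of them were higher and 2, 6 and 2 lower. They passed (adjusted p = 3.32e-05, 1.88e-07 and 1.78e-10), but with an estimated correlation the adjusted p = 0.184, 0.0563 and 0.184. No set call was made for proline and glutamate (2 higher, 7 lower of 22; median -0.04, turning to 0.34), ATF4 (6 and 4 of 22), unfolded protein (3 and 11 of 20; -0.20, turning to 0.18), p53 (7 and 4 of 24), inflammation (4 and 2 of 25), isolation (7 and 8 of 25; -0.04, turning to 0.34, with a mean of 0.02), myeloid (2 and 0 of 21), lymphoid (0 of 3) or glial genes (1 and 0 of 9; -0.28, turning to 0.09). Under library size alone higher and lower genes of these lists numbered 12 and 2 (proline), 14 and 0 (ATF4), 9 and 1 (unfolded protein), 18 and 0 (p53), 15 and 0 (inflammation) and 16 and 0 (isolation). They numbered 16 and 0 for myeloid, 1 and 0 for lymphoid and 2 and 0 for glial genes. The p53, ATF4, inflammation and myeloid medians went from 0.09, 0.03, 0.13 and 0.22 to 0.47, 0.41, 0.51 and 0.61. The unfolded protein list passed without vector TAC library 3 or PRODH TAC library 1 (adjusted p = 0.0448 and 0.0461), and the myeloid list without PRODH sham library 3 (0.0489).

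Adjusted over the list alone, TAC under PRODH gave 4 higher and 15 lower contractile genes, 0 and 41 nuclear respiratory, 3 and 12 unfolded protein, 8 and 4 p53, 26 and 0 cell cycle, 5 and 10 clock, 1 and 30 ribosomal, 16 and 0 endothelial, 12 and 1 mural, 5 and 0 red cell, and no glial genes, and the other lists kept their counts. The edgeR test with Benjamini-Hochberg adjustment called 4925 genes, 2425 higher and 2500 lower, of which 436 and 99 differed by at least 1 on the log2 scale. Scaling by library size alone moved the median of all genes from 0.02 to 0.40 and the split to 7875 higher and 311 lower, or 96.2% higher against 49.2%. With the fibroblast-marker score as a covariate 267 genes were called, while the median SE of the 4925 genes went from 0.10 to 0.22. With 1.73% of its variance within groups, the score cannot be parted from the surgery.

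The virus contrast after sham compares the PRODH and vector arms without pressure overload. Interferon genes were higher with PRODH in 25 of 27 cases with none lower, 27 adjusted over the list alone (median 1.02), and Ifit1 (3.13 ± 0.263 to 13.7 ± 2.22 CPM, SD, n = 4) and Usp18 (1.85 ± 0.13, log2 ± SE) were among the largest rises of genes of at least 5 CPM with a standard symbol. Per2, a clock gene, rose by 1.95 ± 0.16. Of 18 clock genes 12 were higher and 4 lower (12 and 5 adjusted over the list alone). Dbp (1.39 ± 0.08), Tef (1.01 ± 0.07) and Arntl (-1.92 ± 0.18) are named after their values were seen. Among genes of at least 5 CPM the largest falls were Cdkn1a (31.5 ± 2.43 to 12.5 ± 1.70 CPM), Slc41a3, a magnesium transporter gene (-1.21 ± 0.08), and the transferrin receptor gene Tfrc (-1.17 ± 0.10). Cell-isolation genes were lower in 10 of 25 cases and higher in 3, hypertrophy genes lower in 6 of 19 and higher in 1, and red cell and platelet markers lower in 5 of 6. The p53 and unfolded protein genes were lower in 4 of 24 and 4 of 20 cases with 1 higher in each, and atrial genes lower in 2 of 11. Bmp10, an atrial gene at -4.18 ± 0.29, was at 4.39 to 5.55 CPM in vector sham and at most 0.488 CPM in the other 12 libraries. How atrial tissue was handled in each group is not given in the sources used here. These 8 lists passed camera (adjusted p = 5.81e-101, 5.32e-20, 7.70e-10, 7.02e-09, 7.70e-10, 0.00450, 0.00287 and 2.64e-06) and held with an estimated correlation (1.91e-06, 3.60e-05, 0.0113, 6.05e-04, 0.0297, 0.0297, 0.0297 and 0.0351). The p53 median of -0.01 turned to 0.02 under library size alone. Its mean was -0.09, and the p53 list holds Cdkn1a. The atrial list, with a median of -0.23 and a mean of -0.52, holds Bmp10. Neither list was tested without that gene, so how far each set call rests on it is not known.

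Matrix genes were lower with PRODH after sham in 6 of 36 cases and inflammatory ones in 5 of 25, and fibroblast, myeloid and lymphoid markers were higher in 2 of 16, 7 of 21 (with 3 lower) and 2 of 3. These lists passed camera (adjusted p = 1.29e-04, 0.0200, 4.16e-04, 8.39e-04 and 0.0263), but with an estimated correlation the adjusted p = 0.526, 0.396, 0.393, 0.373 and 0.173. The inflammatory call was lost without vector sham library 3 or PRODH sham library 4 (adjusted p = 0.103 and 0.0551), and the lymphoid call without vector sham library 3 or PRODH sham library 3 (0.0662 and 0.123). No set call was made for contractile (2 higher, 0 lower of 25; median -0.001, turning to 0.02, with a mean of 0.01), proline and glutamate (2 and 2 of 22), fatty acid (1 and 1 of 30), citric acid (0 of 26), nuclear respiratory (0 of 42), mitochondrial respiratory (0 of 13), glycolysis (0 and 1 of 24), branched-chain (0 of 21), ATF4 (1 and 1 of 22), antioxidant (2 and 0 of 27), cell cycle (1 and 0 of 28), ribosomal (0 of 36), endothelial (2 and 1 of 19), mural (0 and 3 of 14; median 0.09 with a mean of -0.12) or glial genes (0 of 9). The glycolysis median of 0.02 went with a test that pointed down. Without vector sham library 1 or PRODH sham library 4 the nuclear respiratory list passed as lower (adjusted p = 0.0221 and 1.74e-04), as did the ribosomal list (0.00691 and 7.89e-06). The mitochondrial list passed without vector sham library 2 or PRODH sham library 4 (0.0339 and 0.0272), and the ATF4 list without vector sham libraries 1 or 4, PRODH sham library 4 or PRODH TAC library 4 (0.0276, 0.0415, 0.0463 and 0.0386).

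Adjusted over the list alone, the sham contrast gave 1 higher and 10 lower hypertrophy genes, 2 and 1 contractile, 4 and 2 proline, 1 and 2 fatty acid, 2 and 1 glycolysis, 0 and 12 matrix, 1 and 3 ATF4, 1 and 6 unfolded protein, 3 and 2 antioxidant, 2 and 6 p53, 1 and 7 inflammatory, 3 and 12 isolation, 1 and 2 cell cycle, 3 and 0 fibroblast, 3 and 4 mural, 12 and 3 myeloid and 0 and 5 atrial genes. The edgeR test with Benjamini-Hochberg adjustment called 704 genes between the virus arms after sham, 395 higher and 309 lower, of which 83 and 38 differed by at least 1 on the log2 scale. With the fibroblast-marker score as a covariate 437 genes were called. Between the virus contrasts after sham and after TAC, 177 genes were higher in both, 130 lower in both and 170 opposite, where independent lists of these lengths would give 73 higher and 76 lower in both. For opposite genes no such number was computed. Across all genes the 2 contrasts correlated at only 0.087, so these counts do not show that the virus effects agree after both surgeries.

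Whether the TAC effect itself differed between the virus arms was tested as an interaction. TAC raised Myh7 by 6.52 ± 0.10 (log2 ± SE, n = 4) under the vector and by 1.11 ± 0.10 under PRODH, a difference of -5.41 ± 0.14, and Comp (-5.30 ± 0.46) and Fmod (-3.78 ± 0.34) also rose less under PRODH. Klhl33 (2.03 ± 0.16), the integrin gene Itgb6 (1.95 ± 0.14) and Phkg1 (1.82 ± 0.14) had the largest differences upward among genes of at least 5 CPM with a standard symbol. All 3 fell under the vector, and under PRODH Klhl33 was at -0.60 ± 0.10, Phkg1 at -0.38 ± 0.09 and Itgb6 at 0.29 ± 0.10. Hypertrophy genes had a lower TAC effect under PRODH in 15 of 19 cases, matrix genes in 33 of 36 and fibroblast markers in all 16, with none higher, while contractile genes had a higher effect in 14 of 25 and a lower one in 1. Clock genes differed in 13 of 18 cases, 12 lower and 1 higher. These 5 lists passed camera (adjusted p = 8.42e-35, 2.26e-64, 2.79e-39, 2.31e-07 and 2.34e-06) and held with an estimated correlation (8.89e-07, 0.00279, 0.00270, 0.0176 and 0.00569). In genes called higher after TAC under the vector the median TAC effect was 0.86 there and 0.32 under PRODH, and in those called lower -0.51 and -0.23. Those medians favour the arm in which the genes were picked.

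Other lists passed camera's interaction test with the preset correlation and not with an estimated one. The TAC effect was higher under PRODH for 14 of 30 fatty acid genes, 14 of 26 citric acid genes (1 lower), 12 of 21 branched-chain genes and 12 of 27 interferon genes (5 lower). It was lower for 10 of 25 inflammatory, 12 of 25 isolation (2 higher), 19 of 36 ribosomal, 14 of 19 endothelial (1 higher) and 15 of 21 myeloid genes. Their adjusted p by camera was 4.04e-07, 1.79e-05, 8.57e-05, 0.00331, 5.08e-04, 0.00119, 7.89e-06, 4.01e-08 and 3.42e-11, and with an estimated correlation the adjusted p = 0.142, 0.201, 0.142, 0.220, 0.162, 0.142, 0.409, 0.142 and 0.0515. No set call was made for proline and glutamate (3 higher, 2 lower of 22), nuclear respiratory (7 and 0 of 42), mitochondrial respiratory (1 and 0 of 13), glycolysis (5 and 5 of 24), ATF4 (4 and 6 of 22), unfolded protein (4 and 3 of 20), antioxidant (4 and 8 of 27), p53 (5 and 8 of 24), cell cycle (4 and 0 of 28), mural (3 and 3 of 14), lymphoid (0 and 2 of 3), red cell (0 and 1 of 6), glial (0 and 2 of 9) or atrial genes (6 and 3 of 11). The proline and glycolysis medians of -0.05 and -0.06 went with tests that pointed up. The nuclear respiratory list passed without vector sham libraries 1, 3 or 4, PRODH sham libraries 3 or 4, vector TAC library 2 or PRODH TAC libraries 1 or 2 (adjusted p from 5.50e-04 to 0.0324). The lymphoid list passed without vector sham libraries 1, 2 or 4, PRODH sham libraries 1, 2 or 4, vector TAC library 3 or PRODH TAC libraries 1, 2 or 4 (0.0198 to 0.0449). The antioxidant list passed without vector sham library 2, PRODH sham library 1, vector TAC library 1 or PRODH TAC library 4 (0.0373 to 0.0470). The mitochondrial list passed without vector sham library 2 or PRODH sham library 4 (0.0404 and 0.0345), and the atrial list without vector sham library 4 (0.0372).

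Adjusted over the list alone, the interaction gave 0 higher and 16 lower hypertrophy genes, 15 and 1 contractile, 15 and 0 fatty acid, 15 and 1 citric acid, 3 and 0 nuclear respiratory, 13 and 1 branched-chain, 0 and 34 matrix, 4 and 7 ATF4, 4 and 4 unfolded protein, 4 and 11 antioxidant, 12 and 6 interferon, 0 and 11 inflammatory, 2 and 13 isolation, 2 and 0 cell cycle, 3 and 13 clock, 0 and 23 ribosomal, 1 and 16 endothelial, 3 and 5 mural and 0 and 16 myeloid genes. The edgeR interaction test with Benjamini-Hochberg adjustment called 3764 of 14066 genes, 1540 with a higher and 2224 with a lower TAC effect under PRODH, of which 304 and 792 differed by at least 1 on the log2 scale. With the fibroblast-marker score as a covariate 2 genes were called, while the median SE of the 3764 genes went from 0.16 to 0.57. That score has 1.73% of its variance within groups and cannot be parted from them. Between the TAC contrasts of the virus arms, 1852 genes were higher in both, 1666 lower in both and 136 opposite, where independent lists of the same lengths would give 735, 655 and 1393. This overlap was not computed with library size alone. That scaling called 311 genes lower after TAC under PRODH, so the 1666 depend on the scaling.

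**Figure D3:**
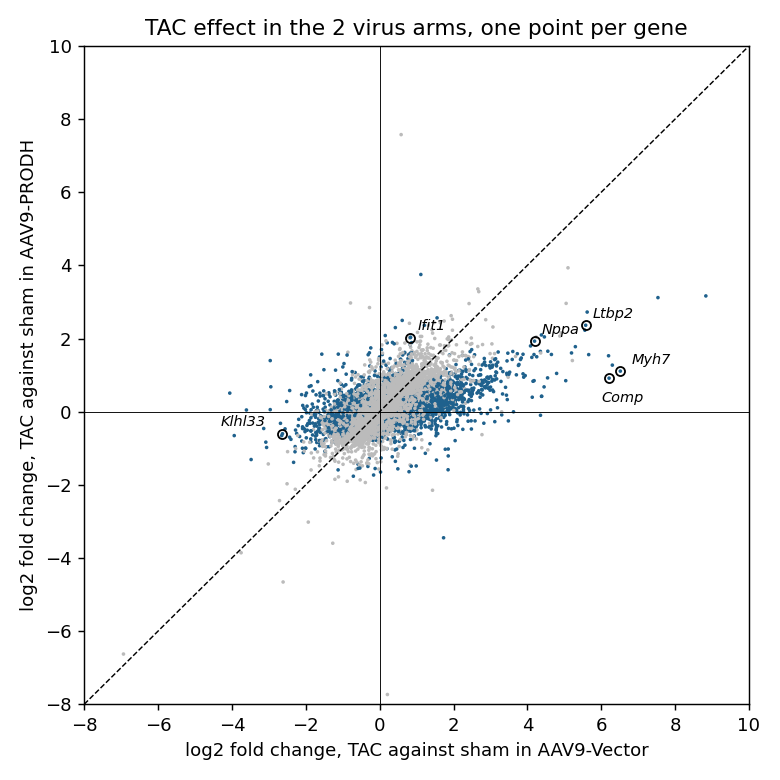
Log2 fold change of TAC against sham under AAV9-Vector (horizontal axis) and under AAV9-PRODH (vertical axis), one point for each of the 14066 tested genes; blue points have an edgeR interaction adjusted p below 0.05 and the dashed line marks equal effects. Myh7 lies at 6.52 and 1.11 and Comp at 6.21 and 0.92, far below the dashed line, while Ifit1 lies at 0.83 and 2.02, above it.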

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

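The tests of the 3 patterns weighed here were chosen after the results had been seen, while the counts of other splits for 4 of the comparisons (all but TAC under the vector) were planned before theirs.

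For 60 of the 72 named genes the TAC effect differed between the virus arms by edgeR's interaction test, against 3764 of all 14066 genes (26.76%). Many named genes were picked for a small p or a large change in these data, so a high share was built in. Values below are log2 differences, PRODH minus vector. Among stress and contractile genes these were Nppa (-2.27), Nppb (-0.70), Myh7 (-5.41), Acta1 (-0.81), Ccn2 (-2.10), Myh6 (0.48), Atp2a2 (0.77), Kcnd2 (1.37), Kcnv2 (1.65) and Kcnj3 (1.24). Among matrix and fibroblast genes they were Postn (-2.28), Col1a1 (-2.48), Cilp (-2.90), Comp (-5.30), Thbs4 (-3.52), Ltbp2 (-3.22), Svep1 (-2.90), Fmod (-3.78), Lox (-2.70), Mfap5 (-2.64) and Pi16 (-2.15). Among genes of proline and fuel metabolism they were Prodh (0.56), Aldh4a1 (0.40), Slc1a5 (-1.85), Ucp3 (1.33), Acaa2 (0.32), Acot1 (0.94), Acsl1 (0.59), Sdha (0.53), Ndufs1 (0.71), Aldh6a1 (0.51) and Scd4 (-1.01).

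Among interferon genes the differences were Ifit3b (0.69), Ifit1 (1.19), Irf7 (0.88), Ddx60 (1.65), Usp18 (0.72) and Ifi44 (1.68), and among stress, growth and ribosomal genes Nupr1 (-2.97), Gpx3 (-1.07), Hsph1 (0.88), Hspa1b (-1.28), Mki67 (1.20), Rpl3 (-0.94) and Rps20 (-0.65). Clock genes stood at Cry1 (-1.08), Nr1d1 (-0.47), Dbp (-1.05) and Per2 (-2.41), and markers of other cells at Pecam1 (-0.56), Plvap (-1.67), Pdgfrb (-0.84), C1qb (-1.16) and Bmp10 (3.28, which rests on its level in vector sham, where the handling of atrial tissue is not given in the sources used here). The others were Klhl33 (2.03), Phkg1 (1.82), Chaer1 (1.77), Itgb6 (1.95), Slc41a3 (0.40) and Tfrc (1.51).

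In 12 of 296 groups of 4 libraries 1 library lay far from the others by Dixon's criterion, where chance alone gives about 1 in 20 groups, or 14.8. Nppa was at 139 CPM in PRODH sham library 4 (108 to 112 in the others), Acot1 at 7.91 in vector sham library 3 (9.11 to 9.34) and Sdha at 539 in PRODH TAC library 2 (575 to 580). Slc1a5 was at 15.2 CPM in vector TAC library 3 (12.7 to 13.0), Gpx3 at 93.2 in PRODH TAC library 4 (84.9 to 85.6) and Mki67 at 2.74 in PRODH sham library 2 (1.45 to 1.58). Hsph1 was at 72.7 CPM in vector sham library 1 (64.0 to 65.1) and 28.9 in PRODH TAC library 1 (27.3 to 27.4). In vector sham library 1 Phkg1 was at 16.2 CPM (13.4 to 13.7) and Itgb6 at 15.4 (12.5 to 12.6). The total count was 20 M in vector TAC library 1 (17 to 17.5 M, with M for mega), and the mitochondrial share 37.9% in vector sham library 2 (40.8% to 40.9%).

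Matrix and fibroblast genes were higher after TAC under the vector and lower with PRODH after TAC. A changed share of cardiomyocyte RNA would move the markers of other cell types alike if the mix of those cells stayed the same. Fibroblast markers exceeded endothelial ones by 1.19 in median log2 fold change after TAC (2.25 against 1.06, permutation p = 1e-05, the smallest that 100000 permutations can give). With PRODH after TAC the difference was -0.936 (-1.39 against -0.45, permutation p = 0.00021). Both p-values come from shuffling genes of the same libraries, which are not independent replicates. They do not measure the spread between libraries. The medians argue only against a changed cardiomyocyte share, with the mix of other cells unchanged, as the whole cause. More fibroblast RNA after TAC remains open, since all 14 fibroblast markers outside the matrix list, which shares the rest of the 16, were called higher, and a change within fibroblasts was not tested apart from it. Whether the fibroblast share carries the changes of other genes cannot be told apart from the groups, because only 1.73% of the variance of the fibroblast score lies within groups.

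Clock genes differed between PRODH and vector after sham. A virus effect of the same size after both surgeries is argued against, since 13 of 18 clock genes had an interaction call. With PRODH 12 of them were higher and 4 lower after sham, and 5 and 8 after TAC. The direction was not lost for all: by group means, Tef, Dbp, Arntl and Nr1d1 differed the same way after both surgeries. Per2 and Cry1 were higher with PRODH after sham and lower after TAC. Collection at different times of day may also part the groups: 8 of 10 genes of the clock's opposed arms were called in opposite directions after sham, 5 higher (Per2, Per3, Dbp, Tef, Hlf) and 3 lower (Arntl, Clock, Nfil3). The labels give no collection time, so this cannot be told apart from an effect of the virus.

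Interferon genes were higher with PRODH after both surgeries. After TAC the median of myeloid markers differed from that of interferon genes by -2.18 (-0.79 against 1.39), and 20 of 21 myeloid markers were lower. That argues against more myeloid RNA as the cause after TAC. After sham the difference was -0.677 (0.35 against 1.02), but both medians were above 0, with 7 of 21 myeloid markers higher and 3 lower. More myeloid RNA after sham is therefore not excluded. Each difference had permutation p = 1e-05, the smallest that 100000 permutations can give, over genes that are not independent replicates. More lymphoid RNA after sham stays open, since 2 of 3 lymphoid markers were higher there (median 0.66). A difference between virus preparations would raise them after both surgeries, as 21 of 27 genes were, and cannot be told apart from an effect of PRODH because each virus is 1 group after each surgery.

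Other splits of the same libraries bear on the counts of genes called. For TAC under the vector only the real split of 35 reached its 7949 genes (1 of 35; highest other 1), and the same held for PRODH against vector after TAC (1 of 35; 6059 against 1), TAC under PRODH (1 of 35; 4925 against 0) and PRODH against vector after sham (1 of 35; 704 against 7). With 35 splits the share cannot fall below 1 of 35. The other splits mix libraries of 2 groups that differ, which widens the spread within each side and keeps their counts low. These splits therefore do not exclude chance, and the labels do not say that the libraries of a group are separate animals. For the interaction 3 of 100 splits, the real one included, gave at least 3764 genes, the highest other 4859. Both larger splits exchanged all 8 TAC libraries between the virus arms, which keeps them divided by virus, together with 2 sham libraries, which points to the structure of the samples. Splits within each surgery also remove the virus effect after TAC, so this count does not bear on the interaction itself.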

How the results depend on the processing

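Choices added after seeing the data were the fits without mitochondrial genes and copies, without vector TAC libraries 3 and 4, and with the fibroblast-marker score; the others were planned. Over all alternatives except single left-out libraries, named genes kept direction and side of the threshold in 1419 cases, lost the call in 75, gained it in 5 and reversed in 19, and with 1 library left out in 1874, 0, 6 and 8 cases. Between shared calls no gene changed direction under any alternative except library size alone (25 genes for TAC under the vector and 52 under PRODH). Requiring a log2 change of at least 1 left 2245 genes for TAC under the vector, 1082 for PRODH after TAC, 535 for TAC under PRODH, 121 for PRODH after sham and 1096 for the interaction, by construction. Library size alone gave 8186 genes for TAC under PRODH, as the scaling moved the median of all genes to 0.40. Without vector TAC libraries 3 and 4 the counts were 6723, 4258, 5118, 791 and 2801, in the same order. With 1 library left out they ranged over 7389 to 8094, 5279 to 6235, 3916 to 5161, 510 to 796 and 3207 to 4110.

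With the fibroblast-marker score as a covariate 7, 40, 267, 437 and 2 genes were called, in the same order. The score has 1.73% of its variance within groups, and the median SE of the genes called without it went from 0.12, 0.11, 0.10, 0.11 and 0.16 to 0.79, 0.51, 0.22, 0.13 and 0.57. Their median absolute log2 fold change went from 0.65, 0.52, 0.45, 0.54 and 0.68 to 0.56, 0.39, 0.39, 0.52 and 0.43, so calls ended with a wider spread and smaller folds. For TAC under the vector Aldh6a1 went to -0.10 and Cdkn1a to 0.01, and for PRODH after TAC Aldh6a1 went to 0.06, Acsl1 to 0.17 and Myh6 to 0.01. With it the TAC effect under the vector reversed for Prodh (0.17), Myh6 (0.17), Aldh18a1 (-0.46), Slc1a5 (-0.35), Nupr1 (-0.34), Mcm6 (-0.27), Pecam1 (-0.40), Pdgfrb (-0.62), C1qb (-0.73) and Hbb-bs (-1.84). The PRODH effect after TAC reversed for Aldh18a1 (0.20), Slc1a5 (0.14), Sdha (-0.044), Ndufs1 (-0.013), Pdgfrb (0.81), C1qb (0.52) and Hbb-bs (0.58), none of them past the threshold. The median SE was 0.79 and 0.51 in these 2 comparisons, so the reversals set no direction. Prodh after TAC was at 0.42 (adjusted p = 0.9998) with it.

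The TAC effect on Prodh under PRODH, near 0, turned to 0.36 (adjusted p = 0.00394) with library size alone and 0.19 with the fibroblast score, and with 1 library left out it ranged from -0.056 to 0.052, with 8 of the values above 0. Prodh after sham passed with 1 CPM in 4 libraries (0.33, adjusted p = 0.0478), with only the sham groups (0.33, 0.0438), without mitochondrial genes and copies (0.34, 0.0465) and without vector TAC libraries 3 and 4 (0.33, 0.0385), and ranged from 0.29 to 0.37 with 1 library left out; the cause was not tested.

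For lists, an estimated correlation ended 37 calls, fry, which asks whether a list moves one way on balance, not against other genes, ended 4 and added 29, and leaving out 1 library ended 8 and added 41; a list that passed in neither setting was not counted as reversed. The replicate number as a block gave 7940, 6125, 4956, 723 and 3872 genes and Prodh values of 0.90 after TAC and 0.33 after sham (adjusted p = 0.0613), and it added calls for antioxidant and lymphoid genes in the interaction (adjusted p = 0.0447 and 0.0460). The numbers do not pair the libraries: same-number correlations ran from -0.129 to 0.168, 3 of 24 were above 0.1, and 5 of 16 libraries correlated best with their own number. The alternative without libraries in which Bmp10 exceeded 1 CPM could not be run, because it removes all 4 vector sham libraries. What depth limits was not tested, since the simulations varied only the size of the change.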

Other observations

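The gene groups and genes described here were chosen after the results had been seen. Of 758 Gene Ontology terms with 20 to 300 measured members, collagen fibril organization had the smallest p for TAC under the vector, with 28 of 35 genes higher and 1 lower (camera adjusted p = 5.28e-30; adjusted p = 0.0177 with an estimated correlation), and for PRODH after TAC, with 30 lower and 2 higher (adjusted p = 0.0246 with an estimated correlation). Angiogenesis genes were higher after TAC in 121 of 182 cases and lower in 21 (adjusted p = 8.46e-12, and adjusted p = 0.0711 with an estimated correlation). All 19 endothelial and all 16 fibroblast markers were higher in the same comparison (medians 1.06 and 2.25). Mitochondrial translation genes were lower in 28 of 34 cases (adjusted p = 1.03e-05, and adjusted p = 0.333 with an estimated correlation). With PRODH after TAC, genes of the response to hypoxia were lower in 58 of 116 cases and higher in 8 (adjusted p = 1.37e-05, and adjusted p = 0.105 with an estimated correlation), while genes of the response to virus were higher in 32 of 62 and lower in 13 (adjusted p = 4.73e-11, and 0.00392 with an estimated correlation). Genes of the cellular response to interferon-beta were higher with PRODH after sham in 23 of 44 cases and lower in 1 (adjusted p = 3.89e-04 with an estimated correlation).

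Cdkn1a, the p21 cell cycle inhibitor, was lower with PRODH after both surgeries, by -1.34 ± 0.09 (log2 ± SE) after sham and -1.53 ± 0.08 after TAC, and its interaction of -0.20 did not pass (edgeR adjusted p = 0.254). Nr4a1, an immediate early gene, was likewise at -1.10 ± 0.08 and -1.11 ± 0.08. It belongs to the list of genes that cell isolation induces. With PRODH that list was lower in 10 of 25 cases after sham (3 higher) and in 20 after TAC (1 higher). A difference in cell isolation between the virus arms was not tested. Tfrc, the transferrin receptor gene, was at -1.17 ± 0.10 with PRODH after sham, and TAC raised it by 1.25 under PRODH. Bmp10, a gene of atrial muscle, was at 4.39 to 5.55 CPM in the 4 vector sham libraries and at most 0.488 CPM in the other 12, and how atrial tissue was handled in each group is not given in the sources used here.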
